A study of Mus musculus with 8 samples.

How the data were processed

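MicroRNA (miRNA) was measured in whole kidney tissue of male C57BL/6 mice aged 8 weeks, 7 days after unilateral ureteral obstruction (UUO) or sham surgery. There were 4 samples per group and 1 array per sample. Per the labels' protocols, total RNA was dephosphorylated, labelled by ligation of a Cy3 nucleotide and hybridized to an Agilent 1-colour miRNA array. The labels number the samples within each group, Sham 1, 2, 3 and 8 and UUO 1, 2, 3 and 4, and do not state in words that each came from a different mouse. If samples shared an animal, the p-values would measure the spread between samples only.

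Per the file headers, the deposited spot intensities were made with Agilent Feature Extraction 10.7.3.1, with a spatial background surface subtracted, no multiplicative detrending and probe positions on mouse build mm9. The processed intensity of each spot is linear, can be negative and was not normalized between arrays by the authors. The same files hold a total intensity per miRNA, which the software sums over the probes it calls detected and sets to 0.1 where none is. The deposited table of the whole series holds ratios: each value equalled the total intensity per miRNA times 1 factor per array, divided by that miRNA's median over the arrays. The basis of the factor is not given in the sources used here. Its log2 ran from −0.38 to −0.15 in the UUO arrays and from 0.15 to 0.36 in the Sham arrays, a mean difference of −0.51. The column medians of that table were 1.11, 1.26, 1.28 and 1.11 for Sham 1, 2, 3 and 8 and 0.809, 0.903, 0.867 and 0.766 for UUO 1 to 4. The table was used as an alternative.

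Each array held 56430 spots for 1881 mouse miRNAs, with 4415 probes. Control spots and spots flagged as population or non-uniformity outliers (2.64 to 2.95% per array) were left out, and the remaining spots of a probe were averaged. A probe was detected on an array when more than 50% of its spots were well above background. Between 720 and 800 probes (16.3 to 18.1%) were detected per array, and no spot was saturated. Each array was divided by its 75th percentile over the 623 probes detected on all 8 arrays. Signals were then raised to a floor, the highest over the arrays of the lowest scaled signal of a detected probe (log2 −4.89), and log2 was taken. All signals below are log2 of this scaled signal. A miRNA was represented by its probe with the highest mean over the 8 arrays. Ties at the floor were broken by the mean unlogged signal, a detail set after the data were seen. The 408 miRNAs detected on at least 4 of the 8 arrays were tested.

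The only comparison was UUO against Sham, with 4 arrays each. It was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with group as the only term. Adjusted p-values are Benjamini-Hochberg values over the 408 tests, and a miRNA was called at an adjusted p under 0.05. Fold changes are UUO over Sham, with the standard error (SE) of the fit on the log2 scale. Where a miRNA was not well above background on any array of a group, its change is given as a bound: the mean of the other group against the mean of the lowest detected signal of the arrays, or of its own signal where that was higher. The bound compares means and makes no allowance for the spread of the measured group, so 'at least' below refers to those means only. The number of arrays limits the precision. Data were simulated with the measured means and spreads of the 408 miRNAs and 120 changed miRNAs per run. This fit recovered 87.9% of log2 changes of 0.5, 98.8% of changes of 1 and 99.9% of changes of 2. Of its calls 3.71% were false. The simulated miRNAs varied independently, with changes of random sign and without a floor, scaling or slide row. These rates describe the fit alone and leave out errors from those sources.

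A total of 22 lists of miRNAs (families, genomic clusters and miRNAs known from particular cell types) were fixed before the data were examined, as were the groups, the tests, all but 1 of the alternatives and the rule for the miRNAs named. The lists were leukocyte, fibroblast and smooth muscle, kidney fibrosis and injury, red blood cell, endothelial, kidney enriched, striated muscle, neural, liver, hypoxia, the let-7, miR-15 and miR-16, miR-29, miR-30, miR-181 and miR-200 families, miR-17-92 with its paralogs, miR-34 with miR-449, the miR-23-27-24 clusters, the Dlk1-Dio3 cluster, the Sfmbt2 intron cluster, and miRBase entries of the kind often taken for fragments of other short RNAs. The 19 lists with at least 3 tested members were tested with camera (preset correlation 0.01, 2-sided), with an estimated correlation and fry as alternatives. The rule named the 10 largest called changes in each direction among miRNAs detected on at least 3 of 4 arrays of each group whose group ranges did not overlap, up to 5 in each direction detected on 4 arrays of one group and 0 of the other, up to 3 called members of each list (or the 2 brightest members where none was called), every tested member of lists with fewer than 6, and miR-21a-5p. It took 76 miRNAs, of which the text gives a part. miRNAs named outside it are said to be chosen after their values were seen.

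The alternatives were other scalings (the percentile over all mouse probes, quantile normalization, none), normexp background correction with an offset of 50, the total intensity per miRNA, the deposited ratio table, the mean of a miRNA's probes, no filter or detection on all 8 arrays, a halved or doubled floor, an eBayes trend, blocks, and each array left out. Scaling to the 4 dmr control features was added after the data were seen. All 8 arrays were on 1 slide and in 1 scan. The Sham arrays filled slide row 1 and the UUO arrays slide row 2, so row and group cannot be told apart, and each slide column held 1 array of each group. The control features of the array were not normalized and are given separately. Probe positions are those in the files, and 186 of the 408 miRNAs had none.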

Results

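The kidney miRNA profile after ureteral obstruction, an injury that leads to inflammation and fibrosis of the kidney, was compared with that after sham surgery. miRNA was measured on 8 arrays, 4 of Sham kidneys and 4 of UUO kidneys, all taken 7 days after surgery. Before scaling, the 75th percentile of the detected signal was 406 ± 8.67 (SD, n = 4) in Sham and 465 ± 22.2 (SD, n = 4) in UUO arrays. The number of detected probes was 734 ± 15.8 (SD) in Sham and 779 ± 26.7 (SD) in UUO. Correlations between arrays over the tested miRNAs ran from 0.991 to 0.999 within groups and from 0.948 to 0.964 between groups. The first principal component, which separated the groups, held 84.5% of the variance.

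Compared with Sham kidneys, UUO kidneys had higher levels of miR-21a-5p, of the miR-199 and miR-214 miRNAs and of miRNAs typical of leukocytes, and lower levels of the miR-30 family, the miR-29 family and miR-192. miR-21a-5p, a miRNA linked to fibrosis in many organs, rose 5.90-fold (log2 fold change 2.56 ± 0.04 (SE), adjusted p = 3.2e-09, n = 4 per group, limma). Of the 408 miRNAs tested, 162 were higher and 113 lower in UUO, and 133 were not called. At least 2-fold changes were found for 51 higher and 21 lower miRNAs. The 4 UUO values all lay on one side of the 4 Sham values for 248 of the 275 called miRNAs, and for 250 of all 408, where chance would give 2.86%.

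The balance of the directions and the sizes of the changes depended on the scaling. With the scaling used here 58.9% of the calls were higher and the median log2 fold change of all tested miRNAs was 0.06. With the percentile over all mouse probes, 194 were higher and 84 lower (median 0.19), and without scaling 212 were higher and 77 lower (median 0.26). Quantile normalization gave 127 higher and 162 lower (median −0.04), and normexp correction gave 122 higher and 156 lower (median −0.03). The total intensity per miRNA gave 109 higher and 217 lower among 499 tested (median −0.23), and the deposited ratio table gave 118 higher and 207 lower (median −0.20). Scaling to the dmr control features, added after the data were seen, gave 237 higher and 64 lower (median 0.33). Across these 8 settings 142 of the 275 miRNAs were called in the same direction each time, 79 of them higher and 63 lower, and no miRNA with a change of at least 2-fold turned its direction. The number of miRNAs at least 2-fold higher ran from 18 to 73 and of those at least 2-fold lower from 5 to 72. Among miRNAs detected on at least 3 of 4 arrays of each group, the 10 largest changes in each direction, 20 in all, were called in the same direction in all 8 settings, but their fold changes differed between settings by 1.46 to 3.89 times. The log2 change of miR-146b-5p ran from 1.17 to 2.94, that of miR-21a-5p from 2.26 to 2.84 and that of miR-30c-1-3p from −2.62 to −0.66.

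**Figure D1:**
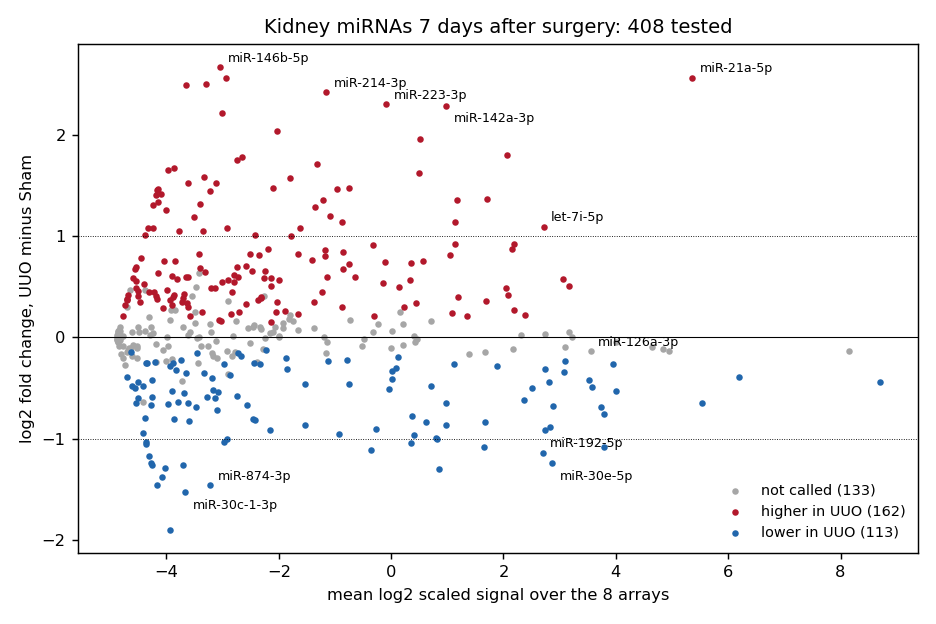
Log2 fold change (UUO minus Sham, vertical axis) against mean log2 scaled signal over the 8 arrays (horizontal axis) for the 408 tested miRNAs. Red points are the 162 miRNAs called higher in UUO, blue points the 113 called lower and grey points the 133 not called, with dotted lines at 2-fold; changes of at least 2-fold occur over most of the range of signal.

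Among miRNAs detected on at least 3 of 4 arrays of each group, the 10 with the largest increases were miR-146b-5p, miR-21a-5p, miR-132-3p, miR-214-3p, miR-223-3p, miR-142a-3p, miR-5121, miR-142a-5p, miR-199a-5p and miR-199a-3p, with log2 fold changes from 2.66 ± 0.07 to 1.80 ± 0.07 (SE). miR-146b-5p, a target of NF-κB signalling, rose 6.34-fold by its brighter probe (adjusted p = 3.07e-08) and its other probe, which was at the floor in Sham, also rose. Its probe is listed at chromosome 19, 46417284 to 46417301 (mm9), and differs by 2 bases from that of miR-146a-5p. The miR-21a-5p probe is listed at chromosome 11, 86397588 to 86397607. miR-132-3p rose 5.90-fold (2.56 ± 0.07). miR-21a-3p, detected on 2 of 4 Sham arrays and chosen after its value was seen, rose 5.66-fold. A further 20 miRNAs were detected on 4 UUO arrays and on 0 Sham arrays. These included miR-511-3p, encoded in an intron of the macrophage gene Mrc1, at least 5.99-fold higher, miR-375-3p, at least 2.94-fold higher, miR-130b-3p, at least 2.92-fold higher, and miR-214-5p, at least 2.82-fold higher.

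By the same limit on detection, the 10 largest decreases were those of miR-30c-1-3p, miR-874-3p, miR-193a-5p, miR-193a-3p, miR-190a-5p, miR-192-3p, miR-30e-5p, miR-192-5p, miR-30e-3p and miR-30c-5p, from −1.53 ± 0.11 to −1.08 ± 0.07 (SE, log2). miR-30c-1-3p was 2.88-fold lower by its brighter probe (adjusted p = 6.36e-06), and its other probe, which was at the floor in UUO, was also lower. miR-874-3p was 2.74-fold lower (adjusted p = 6.34e-08). Of the 8 miRNAs detected on 4 Sham arrays and on 0 UUO arrays, miR-7080-5p was at least 4.67-fold lower, miR-6904-5p at least 3.45-fold lower, miR-6975-5p at least 2.99-fold lower, miR-6401 at least 2.96-fold lower and miR-504-3p at least 2.83-fold lower, but miR-6904-5p and miR-504-3p were not called with no filter. These 5, and 7 of the 8, were lowest among the Sham arrays on Sham 1.

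All 9 tested members of the leukocyte list rose (9 also when adjusted over the list alone), with a median log2 fold change of 2.03. Where every member of a list was called over all 408 tests, the adjustment over the list alone had to call all of them. It adds no support there. miR-223-3p, a myeloid miRNA, rose 4.92-fold (2.30 ± 0.07), and miR-142a-3p, found across blood cell lineages, rose 4.86-fold (2.28 ± 0.07). camera gave an adjusted p of 0.000111 for the list with the preset correlation, and the adjusted p = 0.458 with an estimated correlation. In the kidney fibrosis and injury list, 10 of 12 members rose, 1 fell and 1 was not called (11 called when adjusted over the list alone), with adjusted p = 0.000272 by camera and adjusted p = 0.178 with an estimated correlation. Among them, miR-18a-5p rose 3.37-fold (1.75 ± 0.06). The member that fell was miR-212-3p (−0.41 ± 0.07), named after its value was seen, and miR-34a-5p was at −0.16 ± 0.17. This list shares 3 members each with the leukocyte list and the fibroblast list, so their tests are not independent.

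In the fibroblast and smooth muscle list, 7 of 10 members rose and 3 were not called (8 called when adjusted over the list alone). There were 5 that rose and 3 that fell with the total intensity and with the deposited ratios, and with quantile normalization 6 rose and 3 fell, with normexp correction 6 rose and 2 fell, and with the dmr scaling 9 rose and 0 fell. The list was not called (camera adjusted p = 0.0523, and adjusted p = 0.607 with an estimated correlation). Of the 7, 5 were miR-199 and miR-214 members and 2 were miR-143 members. miR-214-3p rose 5.35-fold (2.42 ± 0.06), miR-199a-5p 3.87-fold (1.95 ± 0.07) and miR-199a-3p 3.47-fold (1.80 ± 0.07), and the probe of miR-199a-5p differs by 1 base from that of miR-199b-5p. The miR-199a-3p probe is listed at 1 position, on chromosome 2, and whether it separates miR-199a-3p from miR-199b-3p was not tested. Of the smooth muscle miRNAs, chosen after their values were seen, miR-143-5p (0.37 ± 0.06) and miR-143-3p (0.24 ± 0.07) rose and miR-145a-5p was at −0.15 ± 0.07, and each changed sign under other scalings. With miR-214-5p at its bound the list's median was 0.93, against 0.88 as fitted.

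All 11 tested members of the list of miR-17-92 and its paralogs, a group linked to cell proliferation, rose (11 also when adjusted over the list alone), with a median log2 fold change of 0.74. camera gave adjusted p = 0.000151, and adjusted p = 0.508 with an estimated correlation. Besides miR-18a-5p, miR-19a-3p rose 1.79-fold (0.84 ± 0.07) and miR-20a-5p 1.76-fold (0.81 ± 0.05). The probes of miR-20a-5p and miR-17-5p differ by 1 base, as do those of miR-19a-3p and miR-19b-3p. Of the miR-15 and miR-16 family 5 of 6 members rose, led by miR-15b-5p (0.92 ± 0.05), but 1 rose and 1 fell with the total intensity (median −0.01) and with the ratio table, and 3 rose and 1 fell with quantile normalization. Of the miR-34 and miR-449 list, miR-34c-5p (1.18 ± 0.07) and miR-34b-5p (0.82 ± 0.09) rose. The third tested member, miR-34a-5p, was the brightest and was not called (−0.16 ± 0.17). It was called lower with quantile normalization, the total intensity and the ratio table. miR-181d-5p (0.57 ± 0.06), miR-181b-5p (0.26 ± 0.06) and miR-181c-5p (0.25 ± 0.07) rose and miR-181a-5p was at 0.13 ± 0.06, but the sign of miR-181b-5p and miR-181c-5p turned under 3 other scalings, and 1 of the 4 rose and 1 fell with the total intensity and with the ratio table. None of these 3 lists was called, with camera adjusted p of 0.118, 0.285 and 0.192 and, with an estimated correlation, adjusted p = 0.673, 0.680 and 0.673.

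All 8 tested members of the miR-30 list, a family abundant in kidney epithelium, fell (8 also when adjusted over the list alone), with a median log2 fold change of −0.83. The list leaves out miR-30b-3p, miR-30c-1-3p and miR-30d-3p, which were also tested. These were called lower in 5, 8 and 6 of the 8 settings. miR-30e-5p was 2.36-fold lower (−1.24 ± 0.07), miR-30e-3p 2.16-fold lower (−1.11 ± 0.07) and miR-30c-5p 2.12-fold lower (−1.08 ± 0.07), and the miR-30e probes differ by 1 base from those of miR-30a. The family's camera adjusted p was 0.000111, and the adjusted p = 0.509 with an estimated correlation of its closely related members. All 6 tested members of the miR-29 family, which targets collagen mRNAs, also fell (6 also when adjusted over the list alone). miR-29c-5p was 2.00-fold lower, miR-29c-3p 1.88-fold lower (−0.91 ± 0.08) and miR-29b-3p 1.60-fold lower (−0.68 ± 0.07). camera gave this family adjusted p = 0.00239, and adjusted p = 0.509 with an estimated correlation. The medians of both families stayed below 0 in the 8 settings, in which 7 or 8 miR-30 members and 4 to 6 miR-29 members fell.

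In the kidney enriched list, 5 of 9 members fell and 4 were not called (5 called when adjusted over the list alone). miR-192-5p was 2.20-fold lower (−1.14 ± 0.11), miR-192-3p 2.40-fold lower (−1.26 ± 0.11) and miR-190a-5p 2.45-fold lower (−1.29 ± 0.09). miR-204-5p, chosen after its value was seen, was at 0.10 ± 0.05, and miR-10a-5p, likewise, at 0.00 ± 0.09, and both changed sign between scalings. In the miR-200 family, a marker of epithelium, 5 of 7 members fell, by at most 0.44 on the log2 scale in miR-200a-3p (−0.44 ± 0.06), and 2 were not called. Of this family 2 members rose and 1 fell without scaling, and 2 rose and 0 fell with the dmr scaling. Of the kidney enriched list 4 rose and 4 fell with the dmr scaling, 3 rose and 4 fell without scaling, and 0 rose and 9 fell with the total intensity. Neither list was called (camera adjusted p = 0.0523 and 0.110, and adjusted p = 0.634 and 0.673 with an estimated correlation).

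**Figure D2:**
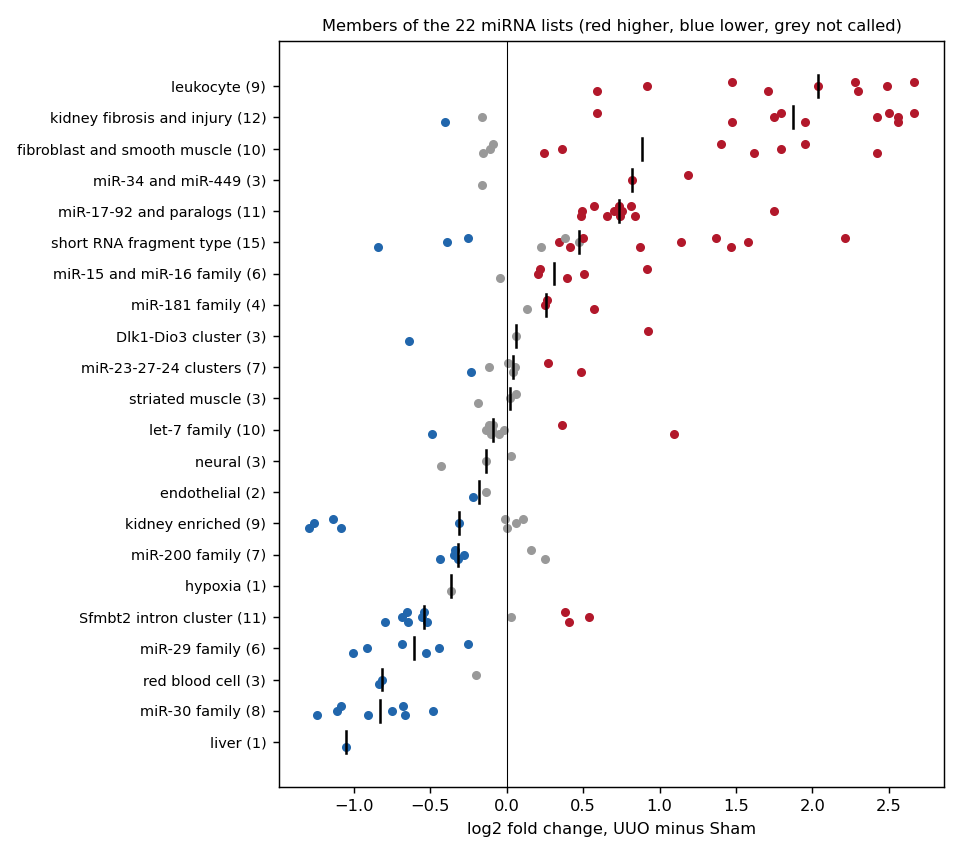
Log2 fold change (UUO minus Sham, horizontal axis) of each tested member of the 22 lists, ordered by their medians (black bars), with the number of tested members in parentheses. Red points were called higher, blue points called lower and grey points not called; all 9 leukocyte members lie to the right of 0 and all 8 miR-30 members to the left.

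With the scaling used here, none of the miRNAs in the endothelial, red blood cell, liver, striated muscle, neural and hypoxia lists was called higher. The endothelial miR-126a-3p was at −0.14 ± 0.06 (adjusted p = 0.0578) and miR-126a-5p at −0.22 ± 0.07 (adjusted p = 0.0169), and both were above 0 with the dmr scaling, miR-126a-3p also without scaling. miR-126a-3p was called higher with quantile normalization and with the dmr scaling (0.14 in each). The erythroid miR-451a fell 1.78-fold (−0.84 ± 0.20) and miR-144-3p 1.76-fold (−0.81 ± 0.23), although their Sham and UUO values overlapped and neither was called with no filter, and miR-486a-5p was at −0.20 ± 0.08. The liver miRNA miR-122-5p was detected on 4 Sham arrays and 0 UUO arrays and was at least 2.60-fold lower, but was not called with a doubled floor (−0.11). No striated muscle miRNA (miR-1a-3p, −0.19 ± 0.21; miR-133a-3p, 0.06 ± 0.07; miR-133b-3p, 0.02 ± 0.23) and no neural miRNA (miR-9-5p, −0.14 ± 0.20; miR-9-3p, −0.43 ± 0.19; miR-128-3p, 0.03 ± 0.05) was called, nor was the hypoxia miRNA miR-210-3p (−0.36 ± 0.23, adjusted p = 0.19). However, miR-210-3p was called lower in 4 of the 8 settings (−0.66 with quantile normalization, −0.27 with normexp correction, −0.70 with the total intensity and −0.66 with the ratio table). Of the neural miRNAs 2 of 3 were lower with quantile normalization, the total intensity and the ratio table and 1 with normexp correction, while 1 was higher without scaling and with the dmr scaling. Of the striated muscle miRNAs 1 was lower with quantile normalization and 1 with normexp correction. The Sham arrays of miR-210-3p were split, at −2.21 and −2.38 on Sham 1 and 8 and −3.15 and −3.14 on Sham 2 and 3. Its UUO mean was −3.08. Those of miR-9-5p were split alike (−2.45 and −2.48 against −3.15 and −3.34), with a UUO mean of −2.99. The split was not particular to these miRNAs. Sham 1 and 8 also lay above Sham 2 and 3 for miR-34a-5p (1.70 and 1.87 against 1.13 and 1.15) and miR-5121 (−3.83 and −3.91 against −4.39 and −4.33). For miR-146b-5p they lay below (−4.45 and −4.49 against −4.28 and −4.27). The red blood cell, striated muscle and neural lists had camera adjusted p of 0.182, 0.831 and 0.632.

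Other families were divided. In the let-7 family let-7i-5p rose 2.13-fold (1.09 ± 0.06), let-7e-5p rose (0.36 ± 0.05), let-7g-5p fell (−0.49 ± 0.06) and 7 members were not called, but 1 rose and 8 fell with the total intensity and with the ratio table, and 8 rose and 1 fell with the dmr scaling. Of the miR-23-27-24 clusters miR-24-2-5p (0.49 ± 0.07) and miR-27a-3p (0.27 ± 0.08) rose, miR-23b-3p fell (−0.23 ± 0.05) and 4 were not called, whereas 0 rose and 5 fell with the total intensity and 6 rose and 0 fell with the dmr scaling. The median of both lists changed sign between scalings. Of the Dlk1-Dio3 cluster only 3 of 36 listed members were detected often enough to be tested, and miR-494-3p rose (0.92 ± 0.18), miR-487b-3p fell (−0.64 ± 0.07) and miR-370-3p was at 0.06 ± 0.17. In the Sfmbt2 intron cluster, whose members have closely similar sequences, 7 of 11 fell and 3 rose, with miR-669c-3p at −0.79 ± 0.12, but 4 fell and 4 rose with the dmr scaling, and miR-669c-3p was not called with a doubled floor. Of the 15 tested entries of the kind often taken for fragments of other short RNAs, 9 rose and 3 fell, with miR-5121 at 2.21 ± 0.15, miR-721 at 1.58 ± 0.24 and miR-2861 at 1.47 ± 0.21; from 6 to 12 rose and from 1 to 3 fell over the 8 settings. These entries had GC-rich probes, with a median GC content of 72.7% against 53.3% for the other miRNAs. camera called none of these 5 lists, with adjusted p of 0.445, 0.938, 0.777, 0.154 and 0.192. For the let-7 list camera pointed down and fry up, and for the miR-23-27-24 and Dlk1-Dio3 lists the median was above 0 while camera pointed down.

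Of the 19 lists tested, camera with the preset correlation called 5, camera with an estimated correlation called 0 (fry called 14), and another split of the 8 arrays into 4 and 4 gave 9. Over all 408 miRNAs 162 were called higher and 113 lower, and among miRNAs outside each list 38.0 to 40.6% were called higher. Counts of members near these shares are not a result about a list. Members also varied together (estimated correlation 0.876 in the miR-30 family and 0.567 in miR-17-92), so their counts are not independent evidence. The group differences above are those of single miRNAs, and the list tests do not settle whether whole lists changed.

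**Figure D3:**
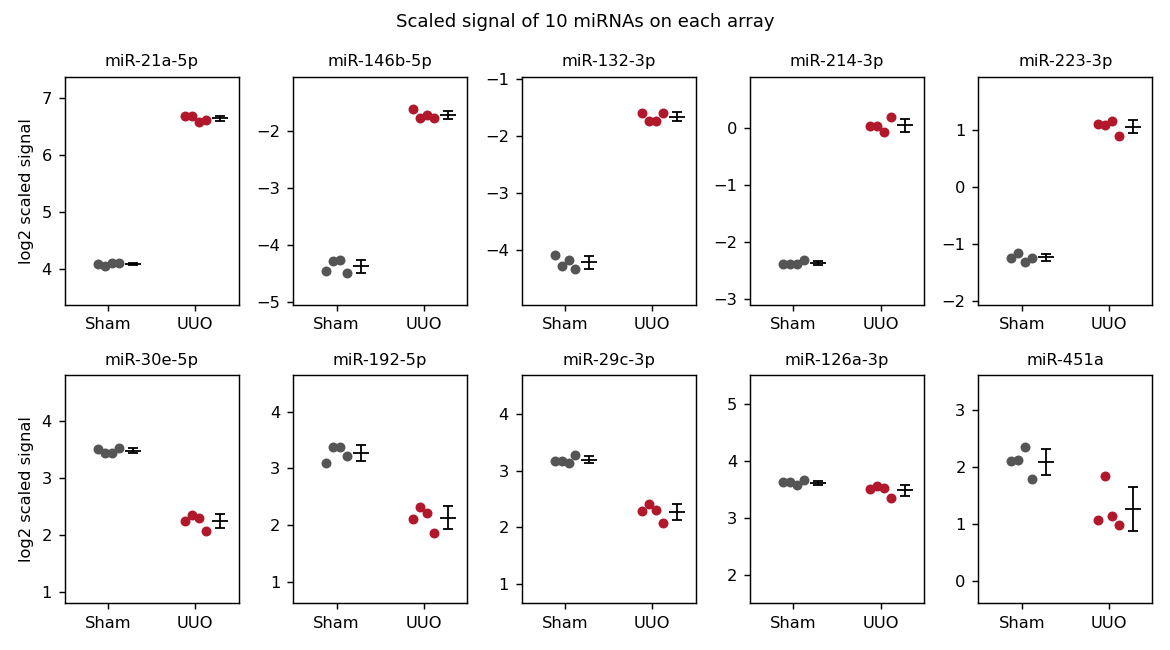
Log2 scaled signal of 10 miRNAs on each of the 4 Sham arrays (grey) and the 4 UUO arrays (red), with the mean and SD of each group beside the points; every panel spans the same range. The groups do not overlap except for miR-451a, and the groups of miR-126a-3p lie close together.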

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

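Of the tests in this part, those of array scaling, of the share of tubule cells, of the slide row, of GC content and of handling were chosen after the result was seen, as was the part of the test of probe choice on miR-132-3p. The 8 arrays were split into 4 and 4 in all 35 ways. Only the real split gave as many as 162 higher, 113 lower, 51 at least 2-fold higher or 21 at least 2-fold lower miRNAs. The other splits reached at most 2 in one direction and 0 at 2-fold. They mix Sham and UUO arrays, so the group difference adds to their spread and lowers their counts. Ranking first of 35 is the most this test can show, and it does not separate group from slide row. Chance is not excluded for the 5 lists called by camera with the preset correlation, since 13 of the 35 splits gave as many and the highest of the others gave 9.

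Leukocyte miRNAs rose while the miR-30 family fell. Over the 8 scalings the leukocyte median ran from 1.17 to 2.31 with 8 or 9 of 9 members called higher, and the miR-30 median came no nearer to 0 than −0.5508 (log2, with the dmr scaling) with 7 or 8 of 8 called lower, which argues against the choice among these scalings as the source. A lower share of tubule cells alone would raise endothelial and leukocyte miRNAs alike. The leukocyte minus endothelial difference within an array rose by 2.009 instead (log2, 95% interval 1.90 to 2.12). The endothelial list was only the 2 arms of miR-126a, and both lists' values were known when the test was chosen. Whether endothelial cells kept their share was not tested, so other changes in cell shares are not excluded. The Sham arrays filled one slide row and the UUO arrays the other. The unscaled control features changed between the rows by −0.8325 (miRNABrightCorner30) to 0.72 (mr_1). What they detect is not given in the sources used here. Without scaling, the miR-30 median was −0.63 and the leukocyte median 2.23. The largest control change exceeded the first in size but not the second. The leukocyte minus miR-30 difference within an array rose by 2.69 (log2, 95% interval 2.50 to 2.89). A row effect that multiplied all spots equally would not change this difference, so the value argues against such an effect alone. One that added an equal amount to all spots would change dim members most, and it was not tested. A row effect that differs between spots cannot be told apart from that of obstruction. Beside these row effects, more leukocytes or more miRNA per leukocyte may account for the rise of the leukocyte list, and these values do not separate them. Which cells of the whole kidney tissue gave the signal was not measured, so a leukocyte origin of the rise is not shown.

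Of the 15 entries of the fragment kind, 9 rose. Removing each array's trend with GC content left 8 of the 9 called higher, which argues against GC content as the whole source, although the list's median fell from 0.47 to 0.17, against 0.31 when the arrays were only centred. The list varied together within groups (mean correlation 0.342, above 97.2% of 10000 random lists matched on signal), and its SE was larger than that of other miRNAs (median 0.15 against 0.08). The groups' list means were separated by a gap of 0.1649, less than the range within Sham (0.492). Both values rest on Sham 1, whose list mean was −0.74, against −1.13, −1.23 and −1.08 on Sham 2, 3 and 8. The UUO list means ran from −0.58 to −0.30. A handling difference between arrays therefore cannot be told apart from an effect of obstruction with these arrays.

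miR-132-3p and miR-212-3p are processed from the same genomic cluster, yet the first rose and the second fell. The choice between the detected probes of each miRNA does not account for this. Both probes of miR-132-3p rose (2.56, and 2.61 from a Sham signal near the floor), and both of miR-212-3p fell (−0.41 and −0.3417, log2). The shorter probe of each lies whole within the longer (15 within 16 bases, and 13 within 14). Their agreement therefore says nothing on what else the sequence may bind. The fall of miR-212-3p stayed below 0 in each of 8 scalings (−0.73 to −0.13) and was called in 7. Different decay or processing of the 2 miRNAs may account for it, as may binding of another RNA by the probes, and neither was tested. In Sham the brighter probe of miR-212-3p was at 0.22, against −4.22 for that of miR-132-3p. The cause of this gap between the probes was not tested either.

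A single array lay apart from the other 3 of its group in 7 of the 141 groups of values of the named miRNAs, where chance gives about 7.05. In 11 further groups every array was at the floor, and these cannot show this. The check looks for 1 array against 3, so it cannot show a split of 2 against 2, such as that of Sham 1 and 8 from Sham 2 and 3. The gap, as a share of the group's range, was 0.864 for miR-21a-5p in Sham (Sham 2 at 4.04, the others at a mean of 4.09). It was 0.987 for miR-214-3p in Sham (Sham 8 at −2.31, the others at −2.38) and 0.85 for miR-5121 in UUO (UUO 2 at −2.15, the others at −1.82). It was 0.85 for miR-7080-5p in Sham (Sham 1 at −3.65, the others at −2.78), 0.911 for miR-6904-5p in Sham (Sham 1 at −4.62, the others at −3.04) and 0.843 for miR-504-3p in Sham (Sham 1 at −4.81, the others at −3.35). It was 1.00 for miR-486a-5p in UUO, where UUO 2 was at −4.81 and the others at the floor of −4.89.

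Of the 10 control features of the array, of which the 4 dmr features served as a scaling above, 4 had every unscaled UUO signal above every Sham signal and 3 had every UUO signal below. mr_1 was 1.65-fold higher in UUO, hur_2 1.23-fold, hur_4 1.18-fold and hur_6 1.25-fold, while miRNABrightCorner30 was 1.78-fold lower, dmr_31a 1.15-fold and dmr_285 1.06-fold (exact permutation p = 0.0286 each, the smallest 4 against 4 allows, 2-sided, adjusted p = 0.0408 over the 10 features). The scaling factor itself was higher in UUO by 0.19 on the log2 scale, and relative to it mr_1 was higher by 0.53 and miRNABrightCorner30 was at −1.03.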

How the results depend on the processing

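Scaling to the dmr control features was chosen after the data were seen. The counts stayed within 1.5 times their values (162 higher, 113 lower, 51 and 21 at least 2-fold, 5 lists) except as follows, and the cause was not tested unless given. Quantile normalization gave 33 miRNAs at least 2-fold lower. normexp correction gave 18 at least 2-fold higher and 5 at least 2-fold lower; its offset of 50 is added to every signal, which pulls dim folds toward 0. The total intensity per miRNA gave 217 lower and 72 at least 2-fold lower, and the deposited ratios gave 207 lower and 67 at least 2-fold lower, each with 499 miRNAs tested. A doubled floor gave 10 at least 2-fold lower, since it raises dim signals. The dmr scaling gave 64 lower and 12 at least 2-fold lower. The list count was 9 with no filter (1881 miRNAs tested), 0 with an estimated correlation and 14 with fry. Leaving out each array gave 147 to 171 higher, 106 to 117 lower, 48 to 55 and 17 to 25 at least 2-fold, and 5 to 7 lists; between 6 and 22 of the 275 calls were lost and 0 changed sign.

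Over the 8 scalings the sign turned in at least 1 for 55 of the 275 called miRNAs (35 called higher, 20 lower), whose median size was 0.25 and largest 0.49 (log2). With quantile normalization 3 and with the dmr scaling 2 were called in the opposite direction. Among the named miRNAs that were called, the signs that turned were those of miR-181b-5p (−0.155 with quantile normalization, −0.103 with the total intensity, −0.0623 with the ratio table), miR-181c-5p (−0.0289, −0.135 and −0.0950), miR-27a-3p (−0.0403 with the total intensity, −6.47e-05 with the ratio table), and, with the dmr scaling, miR-126a-5p (0.0564) and miR-23b-3p (0.0454). Of 76 named miRNAs 44 kept their direction and their side of the threshold under all alternatives. Those that lost their call with the same sign were miR-451a, miR-144-3p, miR-504-3p, miR-6904-5p, miR-181c-5p, miR-27a-3p and miR-126a-5p with no filter, and miR-122-5p, miR-669c-3p, miR-466i-3p and miR-3547-5p with a doubled floor. Under other scalings they were let-7e-5p, miR-16-5p, miR-497a-5p, miR-24-2-5p, miR-23b-3p, miR-126a-5p, miR-181c-5p, miR-200a-3p, miR-200b-3p and miR-200b-5p, with the mean of all probes miR-126a-5p, and with the replicate number as a block miR-144-3p, miR-504-3p, miR-6904-5p, miR-126a-5p, miR-200b-5p and miR-23b-3p. Without Sham 2, miR-27a-3p lost its call (adjusted p = 0.052) and miR-9-3p was called lower (−0.54), as it was without Sham 3 (−0.57). Without Sham 8 miR-486a-5p was called lower (−0.28), and without UUO 2 miR-126a-3p (−0.16).

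The replicate numbers 1, 2 and 3 occur in both groups, but samples with the same number did not deviate together (correlations of −0.000808, 0.124 and −0.303). None of these samples correlated best with its own number. With the number as a block over those 6 arrays, 142 were higher, 84 lower, 45 and 14 at least 2-fold higher and lower, and 6 lists were called; the same 6 arrays without the block gave 146 and 98. With the slide column as a block, 159 were higher and 108 lower. Signal over background limits the dim miRNAs: 335 of the 408 were detected on all 8 arrays, and bounds replace folds for 20 in Sham and 8 in UUO.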

Other observations

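The miRNAs and families in this part were chosen after their values were seen, except miR-193a-3p, miR-193a-5p and miR-130b-3p. The 5 tested members of the miR-378 family fell, from −0.91 ± 0.08 (SE) to −1.03 ± 0.07 (log2), and were called lower under all 8 scalings. miR-378a is encoded in an intron of Ppargc1b, a coactivator gene of mitochondrial metabolism; the miR-378a-3p and miR-378d probes cannot separate these miRNAs, since they match over the shorter probe's length with 0 mismatches. miR-193a-3p, miR-193a-5p, miR-193b-3p and miR-365-3p fell together, with miR-365-3p 2.05-fold lower and miR-193b-3p 1.51-fold lower. miR-455-3p and miR-455-5p were 1.75-fold and 1.77-fold lower, and miR-101a-3p was 1.56-fold lower, although its probe matches that of miR-101c with 0 mismatches and cannot separate the 2.

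miR-182-5p, miR-183-5p and miR-96-5p, which share a genomic cluster, rose 2.39-fold, 2.12-fold and 1.83-fold, although miR-182-5p and miR-183-5p were well above background on only 2 of the 4 Sham arrays. miR-674-3p rose 2.07-fold, and miR-674-5p was detected on 4 UUO arrays and 0 Sham arrays, at least 2.15-fold higher. miR-125a-3p rose 3.44-fold while miR-125a-5p, the other arm of the same precursor, rose 1.27-fold. These miRNAs kept their direction under all 8 scalings. miR-130b-3p was at least 2.92-fold higher, whereas the related miR-130a-3p was at 0.02 ± 0.06. The 5 probes with the highest signal on each array held between 60.4 and 65.6% of the signal summed over 1 probe per miRNA.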
